A study of Mus musculus with 16 samples.

How the data were processed

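RNA of sorted olfactory mucosa cells from S100a5-tauGFP mice was measured on 16 Clariom S mouse arrays, each from the cells of 3 mice. Per the labels' protocols, biotinylated cRNA was made from 50 to 100 ng of total RNA. The authors deposited 1 table of log2 expression values for 28846 probe sets, controls included. It was made with Affymetrix Expression Console, per the submitters' processing notes (its version and the genome build are not given in the sources used here). A label names a gene-level signal from SST-RMA, a robust multi-array average with a signal space transformation. Such a transformation can stretch the scale, so a log2 difference need not equal the log2 ratio of mRNA amounts. Values were used as deposited. Every column was matched to 1 array by its labels, and 0 columns of other samples were present. Groups came from the labels: citrus accord or vehicle, and GFP-positive or GFP-negative, with n = 4 arrays each.

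Gene symbols came from the platform annotation of the probe sets: 19572 probe sets had 1 symbol and were tested, 0 had several, 2634 were without a symbol here, and 6640 were control probes. All 19572 were matched by Entrez identifier to a current gene table, which changed 0 symbols. Where 1 of the 55 symbols with several probe sets was named, the one with the highest mean stood for it. Odorant receptors were 1090 probe sets with Olfr symbols, and 14 trace amine receptors made up 1104 receptors in all. Class I and class II were to be told apart by the newer Or names, which these symbols lack. Instead the MOR family numbers of the gene table were used, with families up to 42 taken as class I. This gave 118 class I and 958 class II receptors, and 1076 of 1090 with a number. Arrays give signal and no read depth. Negative-control probes had a median between 4.84 and 5.37 and a 95th percentile between 8.75 and 9.71 per array, so a receptor below that level cannot be told from background by its level alone, and the precision of each difference is set by the number of arrays.

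Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and 1 spread per probe set over all 16 arrays (empirical Bayes, two-sided), for 5 comparisons. These were GFP-positive minus GFP-negative in vehicle and in citrus, citrus minus vehicle in GFP-positive and in GFP-negative cells, and the difference of the gate differences, which is the effect of citrus on enrichment. Errors given as ± beside a log2 difference are standard errors of this model, and intervals are 95%. Intervals over pools come from 1 value per pool, 4 pools against 4, with equal spread. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. The labels describe the arrays of a group as separate pools of mice, so within a gate p-values measure the spread between pools. The main fit has no term for the pool. Arrays of both gates thus count as independent in it, also where they were taken as the same mice. S100a5 and Omp were also compared by exact permutation of the 4 and 4 arrays. Lists of cell type markers, pathways and receptors, 34 in all, were fixed before the data were examined, as were the design, the rule for named genes and most alternatives. Each list was tested with camera, which compares its genes with all others, at a preset correlation of 0.01 and with an estimated one, and with fry, which tests whether the genes of a list move on balance one way. These p-values were adjusted over the 34 lists within a comparison. All adjusted p beside lists are from camera with the preset correlation unless said otherwise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

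Named genes followed a rule. For the effect on enrichment the receptors past the threshold or, as fewer than 10 passed, the 10 receptors with the smallest p were named. For citrus against vehicle up to 8 genes with the largest change past the threshold in each direction were named, and for the gates up to 8 non-receptor and 3 receptor genes in each direction. Members with the largest change were named for each list, and S100a5 and Omp always. Members were named only for lists called by camera with the preset correlation, a narrowing chosen after values were seen. The gate values of Olfr353 and Olfr704, the receptors past the threshold with the pool as a block, and the values of Camk2n1, Pcdh10 and Sema7a outside the comparisons in which they passed were also named after they were seen.

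GFP-positive and GFP-negative arrays with one number were taken as sorted from the same pool, since the 24 mice make 8 pools of 3, which the labels do not state outright. After group means were removed, such arrays correlated at 0.075 to 0.275 across probe sets. Because they were taken as the same animals, fits with the pool as a block were set beside the results they change. All arrays carried one code in the labels, so no batch could be tested. On simulated data with 50 changed probe sets per size among 19572, the test of the effect on enrichment recovered 16, 47, 46 and 49 at log2 changes of 1, 2, 3 and 4 with 9 false calls. That of citrus in GFP-positive cells recovered 33, 48, 49 and 50 with 16, and that in GFP-negative cells 35, 49, 50 and 50 with 8. The simulated noise was independent between probe sets and between arrays, so these counts leave out any structure of the real samples.

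Alternatives were a trended and robust prior, array weights, leaving out the dimmest 25% of probe sets and testing all probe sets of the table. Others were centring arrays on their median, on the mature OSN marker mean or on the receptor median, cyclic loess, only the groups compared and a minimum absolute log2 change of 1. The last were the pool as a fixed or random block, the number shared by citrus and vehicle pools as a block, and leaving out each pool of mice. The citrus difference averaged over both gates, camera with the pool as a block at either correlation, and the medians of lists without each pool were added after the data were seen. Centring on the receptor median or on mature OSN markers takes out any shift common to those genes by construction. The medians of these lists under their own centring therefore do not test such a shift.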

Results

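Gene expression was measured on Clariom S mouse arrays in sorted olfactory mucosa cells of S100a5-tauGFP mice, whose fluorescent reporter is driven from the gene for S100a5, a calcium-binding protein that olfactory sensory neurons (OSNs) express with activity. In the Kentucky assay, freely behaving mice meet an odorant, and reporter-positive and reporter-negative cells are separated afterwards, so that odorant receptor mRNAs that gain in the positive cells point to receptors of active neurons. Here 24 mice of both sexes, 7 to 12 weeks old, spent 40 h singly in chambers with filtered air at 3.1 L/min. After 26 h they received pulses of 10 s every 20 min, either of filtered air (vehicle) or of citrus accord, a perfumery blend, at 100%. Cells of 3 mice were pooled per sample, and the 16 arrays formed 4 groups with n = 4 arrays each: citrus GFP-positive, citrus GFP-negative, vehicle GFP-positive and vehicle GFP-negative. The table held log2 expression values for 19572 probe sets with a gene symbol, among them 1090 odorant receptor and 14 trace amine receptor probe sets. The highest value per array lay between 19.75 and 19.90. The 95th percentile of negative-control probes lay between 8.75 and 9.71, and between 252 and 458 receptor probe sets exceeded it on a given array. Of 87 named genes 11 lay under it on all arrays, namely Avp, Kit, Sh2d7, Sox2, Notch2, Grk3, Olfr351, Olfr353, Olfr704, Olfr577 and Olfr33, and 45 more on all 4 arrays of at least 1 group. Their differences are bounded by background signal. Arrays of one group correlated at r = 0.985 to 0.992 across probe sets, and GFP-positive with GFP-negative arrays at 0.934 to 0.965. The number of arrays limits the precision of every comparison.

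S100a5 itself checked the gates. Its log2 expression was 17.43 ± 0.10 (SD, n = 4) in citrus GFP-positive, 15.55 ± 0.10 in citrus GFP-negative, 16.86 ± 0.16 in vehicle GFP-positive and 14.94 ± 0.13 in vehicle GFP-negative arrays. It was thus higher in GFP-positive cells by 1.91 ± 0.13 (SE) in vehicle and 1.88 ± 0.13 in citrus, with adjusted p = 8.4e-09 and 8.6e-09, in all 4 pools of either stimulus. Both differences gave an exact permutation p of 0.0286, two-sided, the smallest that 70 assignments of 4 and 4 arrays allow. Between the gates, here and for Omp, this permutation ignores that arrays were taken as pairs from one pool. Kept within 4 pairs, it could not give so small a p. Omp, the olfactory marker protein of mature OSNs, differed by 0.27 ± 0.14 (adjusted p = 0.19, exact permutation p = 0.0286) in vehicle and 0.18 ± 0.14 (adjusted p = 0.40, exact permutation p = 0.114) in citrus. These small differences turned negative (−0.03 and −0.18) when arrays were centred on mature OSN markers and (−0.19 and −0.58) on the receptor median. With arrays centred on the median of all probe sets the Omp differences passed the threshold, with adjusted p = 0.0063 in vehicle and 0.0088 in citrus.

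**Figure D1:**
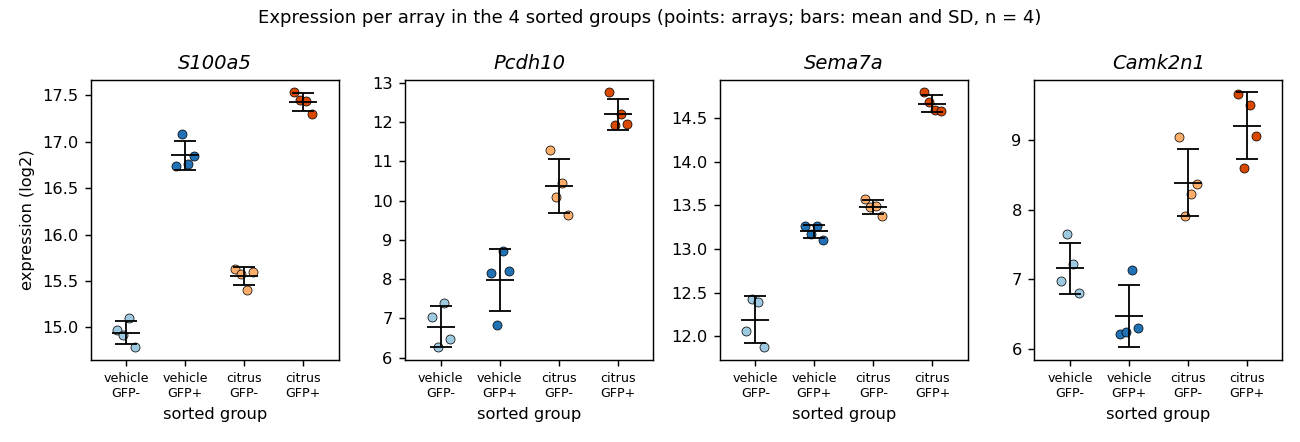
Expression (log2, y axis) of S100a5, Pcdh10, Sema7a and Camk2n1 in the 4 sorted groups (x axis), with points for arrays and bars for mean and SD (n = 4). Pcdh10 averaged 12.20 and 10.36 in citrus GFP-positive and GFP-negative arrays, against 7.98 and 6.79 in vehicle, and S100a5 separated the gates at 17.43 and 15.55 in citrus and 16.86 and 14.94 in vehicle.

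The first question was what the reporter separates without odorant. In vehicle, genes of activity-dependent OSN expression were higher in GFP-positive cells with the preset correlation of the list test, but not past the threshold with an estimated one (adjusted p = 0.0528). Transcripts of white blood cells, dividing progenitors, immature OSNs and microvillous cells were lower. Of 19572 probe sets, 1771 were higher and 1952 lower in GFP-positive cells, 507 and 1406 of them by at least 2-fold. Among non-receptor genes the largest rises belonged to Fxyd2, a regulator of the sodium pump (3.15 ± 0.50, adjusted p = 0.00018), Avp, the vasopressin precursor (2.39 ± 0.24, 8.2e-07), Pcp4l1, a calmodulin-binding family member (2.37 ± 0.25, 1.4e-06), and Lrrc3b (2.05 ± 0.54, 0.012). S100a5, Kcnmb3 (1.89 ± 0.33, 0.00040), a potassium channel subunit, Caly (1.88 ± 0.22, 6.4e-06), an endocytosis adaptor, and Cidea (1.77 ± 0.29, 0.00026), a lipid droplet protein, followed. The largest falls were those of neutrophil and monocyte genes: Lcn2 (−10.30 ± 0.54), Retnlg (−10.13 ± 0.48), Ngp (−9.57 ± 0.42), S100a9 (−9.52 ± 0.48), S100a8 (−9.45 ± 0.50), Chil3 (−9.33 ± 0.56), Fn1 (−9.15 ± 0.43) and Ly6c1 (−9.08 ± 0.42). Their adjusted p lay at or below 1.8e-09. In GFP-positive cells all but Lcn2 and Ngp lay under the 95th percentile of negative-control probes on all 4 arrays, so background bounds the sizes of these falls. Each of these 16 genes differed the same way in all 4 pools. The total of 3723 for GFP+ vs GFP- cells in vehicle became 2466 without vehicle replicate 2 and 2369 without vehicle replicate 4.

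Of the cell type markers in vehicle, all 15 myeloid and lymphoid genes were lower in GFP-positive cells, also 15 adjusted over the list alone, with a median of −4.85 (camera adjusted p = 1.3e-21, and 0.019 with an estimated correlation). Markers of immature OSNs were lower in 6 of 12, such as Gng8, a G protein subunit (−4.04 ± 0.18), and Dpysl3, a growth cone protein (−3.71 ± 0.17). Adjusted over the list alone 1 was higher and 6 lower (1.2e-05, and 0.019 with an estimated correlation). Globose basal and cycling cell genes were lower in 7 of 9, and in 8 adjusted over the list alone (6.8e-08, and 0.019 with an estimated correlation), among them Mki67, a proliferation antigen (−5.35 ± 0.47), and Kit, a progenitor receptor kinase (−3.46 ± 0.32). Microvillous cell genes were lower in 10 of 12, and in 11 adjusted over the list alone (1.9e-09, and 0.03 with an estimated correlation). Trpm5, a cation channel, was at −4.37 ± 0.36 and Sh2d7 at −3.88 ± 0.36. Vomeronasal neuron genes were lower in 4 of 5, adjusted over the list alone also 4 (3.2e-06, and 0.019 with an estimated correlation). Their largest differences were in Gnai2, a G protein that blood cells share (−6.46 ± 0.36), and Tmem176b (−4.81 ± 0.55). In the list of guanylyl cyclase D and Ms4a neurons, 2 of 6 genes were lower, 3 adjusted over the list alone (0.0028, and 0.043 with an estimated correlation), namely Ms4a6c, which macrophages also express (−4.19 ± 0.36), and Pde2a (−3.13 ± 0.38). All 6 of these lists stayed lower under every scaling of the arrays that was tried. With the pool as a block and an estimated correlation together, camera called 0 of the 34 lists in vehicle or in citrus, against 19 and 22 with the block and the preset correlation.

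Other cell type lists in vehicle were called by camera with the preset but not with an estimated correlation. Sustentacular genes were lower in 2 of 11, 3 adjusted over the list alone (0.0057, but adjusted p = 0.508 with an estimated correlation). Of these, Notch2 passed (−1.97 ± 0.26), whereas the sulfotransferase Sult1c1 was at −2.33 ± 0.85 with adjusted p = 0.064 and lower in 3 of 4 pools. Vehicle GFP-negative replicate 1 held Sult1c1 at 7.11 against 11.93 to 12.05 on the other arrays of its group. Without that pool adjusted p was 0.00012, and with the pool as a block 0.0059. Sult1c1 also passed with array weights (0.0319) and with arrays centred on mature OSN markers (0.0441) or on the receptor median (0.0252). Bowman gland genes were lower in 3 of 14, also 3 adjusted over the list alone (0.013, but adjusted p = 0.296 with an estimated correlation). The antimicrobial Ltf, also a neutrophil protein, was at −7.82 ± 0.48 and Sox9, a gland transcription factor, at −4.44 ± 0.40. Their list median was −0.14, but 0.14 with arrays centred on the median, −0.22 without vehicle replicate 1 and −0.32 without vehicle replicate 3. Both measured erythroid genes were lower, also adjusted over the list alone (0.019, but adjusted p = 0.285 with an estimated correlation), Slc4a1, the red cell anion exchanger, at −2.48 ± 0.47 and Alas2, of haem synthesis, at −1.38 ± 0.36 (adjusted p = 0.011, and 0.077 without vehicle replicate 3). Mature OSN markers were higher in 3 of 15, also 3 adjusted over the list alone (0.023, but adjusted p = 0.508 with an estimated correlation), such as the receptor transporter Rtp2 (0.75 ± 0.17) and the chloride channel Ano2 (0.64 ± 0.13). Ano2 did not pass with arrays centred on mature OSN markers (0.0802). The list median of 0.28 became −0.01 with arrays centred on those markers and −0.18 on the receptor median. Centring on those markers takes out any shift of the list by construction. Horizontal basal (1 of 8 lower, adjusted p = 0.438), respiratory ciliated (3 of 8 higher, 0.085) and ensheathing glia (2 of 8 lower, 0.206) lists were not called by camera, with the same counts adjusted over the list alone. By limma 0 of 7 endothelium genes passed, also 0 adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera 0.843). Of 7 stroma genes 0 passed in each of these counts (camera 0.586).

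**Figure D2:**
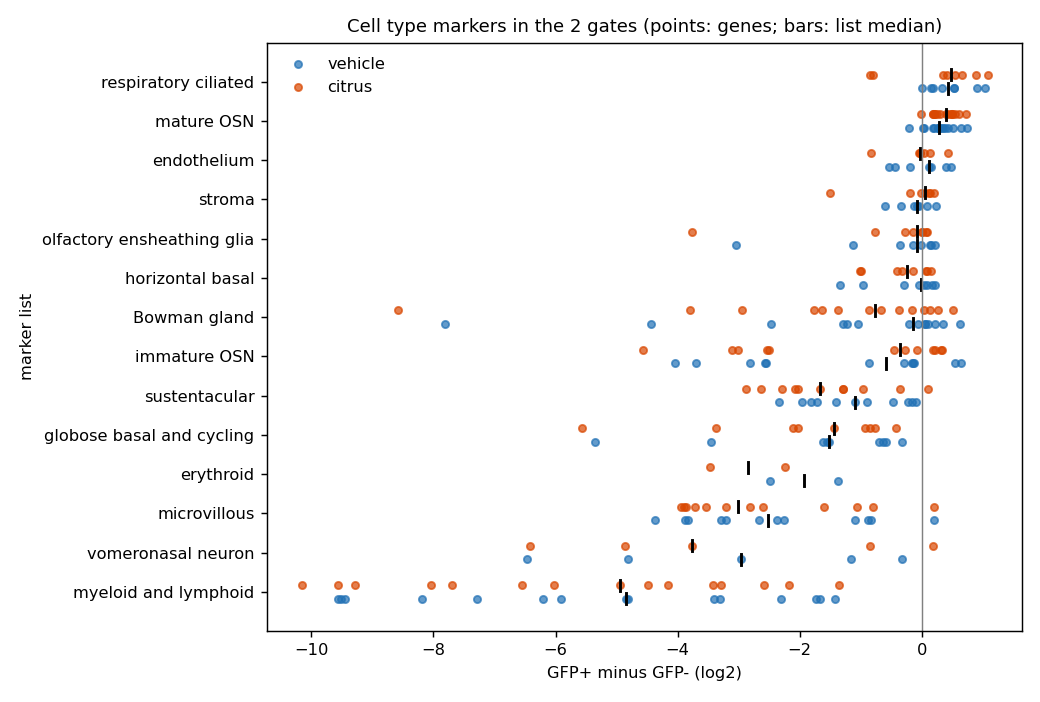
Difference between GFP-positive and GFP-negative cells (log2, x axis) for the genes of each cell type list (y axis), with a point per gene and a bar at the list median, in vehicle (blue) and citrus (orange). The myeloid and lymphoid medians lie at −4.85 in vehicle and −4.95 in citrus. The mature OSN medians lie at 0.28 and 0.39, both below 0 (−0.18 and −0.37) with arrays centred on the receptor median.

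Among pathways in vehicle, 10 of 15 activity-linked OSN genes were higher in GFP-positive cells, also 10 adjusted over the list alone, led by Pcp4l1, Lrrc3b and S100a5 (1.8e-05, but adjusted p = 0.0528 with an estimated correlation). The reporter that sets the gate is driven from S100a5, so this member cannot count as support. The list was not tested without it. Oxidative phosphorylation genes were higher in 10 of 19, also 10 adjusted over the list alone (8.0e-05, but adjusted p = 0.296 with an estimated correlation), such as Sdha of complex II (0.92 ± 0.18) and Atp5j of the ATP synthase (0.81 ± 0.15). Immediate early genes were lower in 8 of 20, 11 adjusted over the list alone (2.9e-05, but adjusted p = 0.296 with an estimated correlation). Egr1 was at −5.12 ± 0.90, Fos at −4.63 ± 0.88 and Btg2 at −4.45 ± 0.46. These transcription factors and growth regulators are also expressed by white blood cells, whose markers were lower in the same arrays. Inflammatory genes were lower in 5 of 14, 6 adjusted over the list alone (7.7e-05, but adjusted p = 0.296 with an estimated correlation), with Lcn2 and the cytokine Il1b (−3.94 ± 0.52). Xenobiotic metabolism genes were lower in 2 of 24, also 2 adjusted over the list alone (0.015, but adjusted p = 0.522 with an estimated correlation), and the top members Sult1c1 and Cyp1a2 (−1.72 ± 0.79, adjusted p = 0.15) did not pass. Cyp1a2 was lower in 3 of 4 pools, and adjusted p was 0.0054 without vehicle replicate 1 and 0.023 with the pool as a block. Olfactory transduction (4 of 18 higher, 1 lower, also 4 and 1 adjusted over the list alone, 0.0817), axon sorting (4 of 14 higher, 1 lower, 4 and 2 adjusted over the list alone, 0.637), endoplasmic reticulum stress (2 of 14 higher, 0 by limma adjusted over the list alone, 0.291), synaptic vesicle (2 of 13 higher, also 2 adjusted over the list alone, 0.062) and NRF2 target (1 of 10 higher, 1 lower, 1 and 2 adjusted over the list alone, 0.704) lists were not called by camera. By limma 0 genes passed, also 0 adjusted over the list alone, in the heat shock (1 of 8 higher and 2 lower at an unadjusted p under 0.05, camera 0.586), dorsal OSN (1 of 2 higher unadjusted, 0.417), ventral OSN (0 of 2, 0.845) and sex-linked (0 of 3, 0.522) lists.

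Receptor genes also differed between the gates in vehicle. Of 1104 odorant and trace amine receptor probe sets, 430 were higher, 226 lower and 448 not past the threshold. Adjusted over the list alone 490 were higher and 258 lower. Their median was 0.57, and 0.10 with arrays centred on the receptor median, which takes out any shift common to receptors. The highest were Olfr536 (6.19 ± 0.47), Olfr372 (5.63 ± 0.30) and Olfr309 (5.53 ± 0.51), and the lowest Olfr1507 (−9.06 ± 0.29), Olfr1297 (−8.52 ± 0.25) and Olfr99 (−8.41 ± 0.43), all with adjusted p at or below 3.5e-07 and in all 4 pools. All 1090 odorant receptors taken as a list had 424 higher and 223 lower members, and 484 and 254 adjusted over the list alone (0.0103, but adjusted p = 0.508 with an estimated correlation). Class I receptors, the phylogenetically older class, had 47 higher and 14 lower of 118, and 54 and 14 adjusted over the list alone (2.7e-05, but adjusted p = 0.508 with an estimated correlation). The largest differences were falls, in Olfr677 (−6.62 ± 0.29) and Olfr69 (−5.49 ± 0.81). Class II receptors had 373 higher and 205 lower of 958, and 426 and 237 adjusted over the list alone (0.024, but adjusted p = 0.535 with an estimated correlation). Trace amine receptors had 6 higher and 3 lower of 14, 6 and 4 adjusted over the list alone (0.438). Vomeronasal receptors had 12 higher of 319 and 0 adjusted over the list alone by limma (camera 0.024, but adjusted p = 0.11 with an estimated correlation). Their median of 0.21 became −0.09 with arrays centred on mature OSN markers and −0.26 on the receptor median. On every array in both stimuli this list averaged 3.35 to 3.72, under the medians of negative-control probes (4.84 to 5.37), so these are differences between background signals.

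The same gate was then compared in citrus. Activity-linked genes were again higher in GFP-positive cells and blood, progenitor, immature OSN and microvillous genes lower. Of 19572 probe sets, 1457 were higher and 2112 lower, 544 and 1589 of them by at least 2-fold. Fxyd2 (3.58 ± 0.50, adjusted p = 3.8e-05), Pcp4l1 (2.5 ± 0.25, 6.0e-07), Lrrc3b (2.13 ± 0.54, 0.0083), Kcnmb3 (1.92 ± 0.33, 0.00029), S100a5, Pcdh10, a protocadherin of axon sorting (1.84 ± 0.38, 0.0018), Avp (1.83 ± 0.24, 1.6e-05) and Kcng1, a potassium channel subunit (1.77 ± 0.54, 0.029), had the largest rises outside the receptors. Lrrc3b did not pass without citrus replicate 4 (adjusted p = 0.0566), nor Kcng1 without citrus replicate 1 (0.0515) or 4 (0.129), nor with arrays centred on mature OSN markers (0.0824) or on the receptor median (0.0953). Kcng1 was also lost with a trended and robust prior (0.0534), with all probe sets tested (0.0558) and with only the groups compared (0.0566). The largest falls were those of Lcn2 (−10.54 ± 0.54), Ngp (−10.16 ± 0.42), Ly6c2 (−10.05 ± 0.42), Retnlg (−9.91 ± 0.48), S100a8 (−9.57 ± 0.50), Chil3 (−9.45 ± 0.56), Hp, the haemoglobin scavenger haptoglobin (−9.42 ± 0.47), and Ly6c1 (−9.42 ± 0.42). Their adjusted p lay at or below 1.3e-09, and all 8 lay under the 95th percentile of negative-control probes on the 4 GFP-positive arrays, so that their sizes are again bounded by background. All of these differed the same way in all 4 pools. Of the genes higher in GFP-positive cells 835 were shared between vehicle and citrus, and of those lower 1678, where independent lists would share 131.8 and 210.6.

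In citrus all 15 myeloid and lymphoid genes were again lower, also 15 adjusted over the list alone (median −4.95, camera adjusted p = 1.6e-22, and 0.017 with an estimated correlation). Globose basal and cycling genes were lower in 8 of 9, all 9 adjusted over the list alone (3.8e-09, and 0.017 with an estimated correlation). Mki67 was at −5.57 ± 0.47 and Kit at −3.38 ± 0.32. Immature OSN genes were lower in 5 of 12, also 5 adjusted over the list alone (9.8e-05, and 0.03 with an estimated correlation). Gng8 was at −4.57 ± 0.18 and Dpysl3 at −3.01 ± 0.17. Microvillous genes were lower in 11 of 12, also 11 adjusted over the list alone (3.1e-10, and 0.029 with an estimated correlation). Sh2d7 was at −3.95 ± 0.36 and Foxi1, an ionocyte transcription factor, at −3.90 ± 0.75. Vomeronasal neuron genes were lower in 3 of 5, 4 adjusted over the list alone (4.1e-05, and 0.03 with an estimated correlation). Gnai2 was at −6.43 ± 0.36 and Tmem176b at −4.86 ± 0.55. Guanylyl cyclase D and Ms4a neuron genes were lower in 4 of 6, also 4 adjusted over the list alone (0.00027, and 0.029 with an estimated correlation). Ms4a6c was at −5.03 ± 0.36 and Pde2a at −3.47 ± 0.38. Activity-linked genes, again with S100a5 among them, were higher in 9 of 15, 12 adjusted over the list alone (1.3e-05, and 0.044 with an estimated correlation). These 7 lists kept their direction under every scaling tried.

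Sustentacular genes in citrus were lower in 4 of 11, 5 adjusted over the list alone (0.00057, but adjusted p = 0.348 with an estimated correlation). Sult1c1 was at −2.89 ± 0.85 (adjusted p = 0.023) and Sox2, a progenitor and supporting cell factor, at −2.64 ± 0.41. Sult1c1 did not pass without citrus replicate 2 (adjusted p = 0.0886), 3 (0.0818) or 4 (0.118), or with a trended and robust prior (0.0611). Bowman gland genes were lower in 6 of 14, also 6 adjusted over the list alone (0.00057, but adjusted p = 0.12 with an estimated correlation). Ltf was at −8.58 ± 0.48 and Sox9 at −3.79 ± 0.40. Slc4a1 (−3.47 ± 0.47) and Alas2 (−2.23 ± 0.36) were the erythroid genes, both lower, also adjusted over the list alone (0.0021, but adjusted p = 0.12 with an estimated correlation). Immediate early genes were lower in 9 of 20, also 9 adjusted over the list alone (4.1e-05, but adjusted p = 0.307 with an estimated correlation). Fos was at −5.56 ± 0.88, Egr1 at −5.27 ± 0.90 and Btg2 at −4.64 ± 0.46. Inflammatory genes were lower in 6 of 14, 7 adjusted over the list alone (2.6e-05, but adjusted p = 0.24 with an estimated correlation), with Lcn2 and Il1b (−5.29 ± 0.52). Xenobiotic metabolism genes were lower in 5 of 24, 6 adjusted over the list alone (0.0013, but adjusted p = 0.374 with an estimated correlation). The top members were Sult1c1 and the cytochrome Cyp2a5, whose −2.30 ± 1.08 did not pass (adjusted p = 0.16). It passed without vehicle replicate 1 (0.0035), with the pool as a block (0.0012), with only the groups compared (0.0151) and with arrays centred on the receptor median (0.0218). Vehicle GFP-negative replicate 1 held Cyp2a5 at 10.28 against 15.70 to 16.16 on the other arrays of its group. Heat shock genes were lower in 3 of 8, 4 adjusted over the list alone, and not called as a list (adjusted p = 0.0928), but called with the pool as a block (0.0096). With an estimated correlation adjusted p was 0.397, and 0.379 with the block as well.

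The mature OSN, olfactory transduction, synaptic vesicle and oxidative phosphorylation lists were called higher in citrus GFP-positive cells by camera with the preset but not with an estimated correlation. Mature OSN genes were higher in 5 of 15, 7 adjusted over the list alone (0.0040, but adjusted p = 0.348 with an estimated correlation). Their median of 0.39 became −0.37 with arrays centred on the receptor median. Ano2 was at 0.72 ± 0.13 and Gng13, a G protein subunit, at 0.61 ± 0.16 (adjusted p = 0.013). Neither passed with arrays centred on mature OSN markers (0.0683 and 0.354). Gng13 did not pass without citrus replicate 2 (0.0921) or 3 (0.0712), and both turned negative (−0.05 and −0.15) with arrays centred on the receptor median. Olfactory transduction genes were higher in 6 of 18 and lower in 1, 7 and 1 adjusted over the list alone (0.0095, but adjusted p = 0.348 with an estimated correlation). Pde1c, a phosphodiesterase of cilia, was at 0.95 ± 0.16 and Grk3, a receptor kinase, at −0.88 ± 0.23 (adjusted p = 0.011, and 0.107 without citrus replicate 4). The list median of 0.40 became −0.36 with that centring. Synaptic vesicle genes were higher in 6 of 13, 9 adjusted over the list alone (0.00053, but adjusted p = 0.24 with an estimated correlation). Of the vesicle phosphoproteins, Syn2 was at 1.06 ± 0.18 and Syn1 at 0.90 ± 0.25 (adjusted p = 0.018). Syn1 did not pass without citrus replicate 3 (0.0923) or 4 (0.137) or with arrays centred on mature OSN markers (0.148), and the list median of 0.50 became −0.26 with arrays centred on the receptor median. Oxidative phosphorylation genes were higher in 3 of 19, 2 adjusted over the list alone (0.0051, but adjusted p = 0.386 with an estimated correlation). Their median of 0.34 became −0.03 with arrays centred on mature OSN markers and −0.43 on the receptor median. Horizontal basal (0.251), ciliated (0.151), ensheathing glia (0.19), endothelium (0.72), stroma (0.731), axon sorting (0.332), endoplasmic reticulum stress (0.808), NRF2 target (0.472), dorsal (0.946) and ventral OSN (0.348), sex-linked (0.946) and trace amine receptor (0.409) lists were not called by camera.

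Receptors in citrus were higher in 468 probe sets and lower in 217 of 1104, with 419 not past the threshold, and in 523 and 251 adjusted over the list alone. Olfr536 (6.53 ± 0.47), Olfr522 (6.31 ± 0.65) and Olfr372 (5.89 ± 0.30) were highest and Olfr1507 (−9.49 ± 0.29), Olfr99 (−8.71 ± 0.43) and Olfr1297 (−8.39 ± 0.25) lowest, with adjusted p at or below 1.1e-06 and in all 4 pools. Background again bounds the sizes for Olfr536 and Olfr372, through their GFP-negative arrays, and for Olfr1507, Olfr99 and Olfr1297, through their GFP-positive arrays. Odorant receptors as a list had 463 higher and 214 lower of 1090, and 518 and 247 adjusted over the list alone (0.00027, but adjusted p = 0.346 with an estimated correlation). Their median of 0.72 became −0.04 with arrays centred on the receptor median, which takes out any shift common to receptors. Class II receptors had 408 higher and 197 lower of 958, and 453 and 228 adjusted over the list alone (0.00059, but adjusted p = 0.348 with an estimated correlation). Their median of 0.70 became −0.06 with that centring. Class I receptors had 51 higher and 13 lower of 118, and 60 and 16 adjusted over the list alone (3.4e-05, but adjusted p = 0.392 with an estimated correlation), again with large falls in Olfr677 (−6.41 ± 0.29) and Olfr69 (−6.25 ± 0.81). Vomeronasal receptors had 14 higher of 319 and 1 adjusted over the list alone (0.033, but adjusted p = 0.12 with an estimated correlation). Their median of 0.20 became −0.17 with arrays centred on mature OSN markers and −0.57 on the receptor median, again between background signals. Only Olfr353 and Olfr704 passed the threshold in opposite directions in the 2 stimuli. Olfr353 was at −1.53 ± 0.29 in vehicle (adjusted p = 0.0011) and 1.24 ± 0.29 in citrus (0.0057), and Olfr704 at −1.14 ± 0.35 (0.028) and 1.16 ± 0.35 (0.025), both under the 95th percentile of negative-control probes on all arrays. In citrus, neither passed without citrus replicate 3 (adjusted p = 0.0667 and 0.236) or with arrays centred on the receptor median (0.11 and 0.213). Olfr704 in citrus also did not pass with arrays centred on mature OSN markers (0.0799) or with only the groups compared (0.0566). In vehicle Olfr704 did not pass without vehicle replicate 1 (0.176), 2 (0.0988) or 4 (0.0521) or with all probe sets tested (0.0511).

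**Figure D3:**
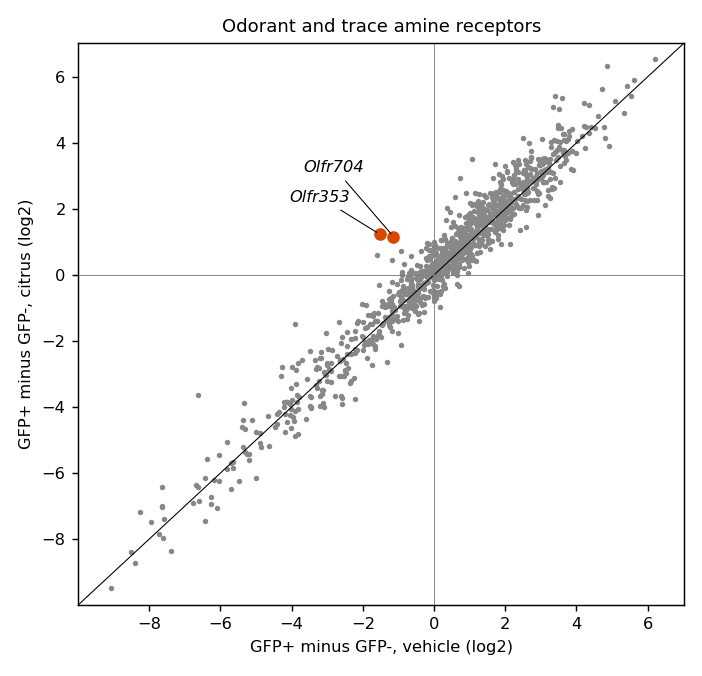
Difference between GFP-positive and GFP-negative cells for 1104 odorant and trace amine receptor probe sets (points) in vehicle (x axis, log2) and in citrus (y axis, log2), with the line of equality. Olfr353, at −1.53 and 1.24, and Olfr704, at −1.14 and 1.16, are marked as the receptors past the threshold in opposite directions.

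The direct effect of citrus was asked first in GFP-positive cells. Pcdh10 rose by 4.22 ± 0.38 (SE, n = 4 arrays per group, adjusted p = 6.4e-05), Camk2n1, an inhibitor of calcium/calmodulin-dependent kinase II, by 2.74 ± 0.28 (0.00017), Olfr353 by 1.83 ± 0.29 (0.046) and Sema7a, a membrane-bound semaphorin of OSN axons, by 1.46 ± 0.14 (8.4e-05). These 4 genes rose and 0 fell by limma, which found 794 probe sets at an unadjusted p under 0.05, 404 higher and 390 lower, where chance gives 978.6. For each of the 4, all 4 citrus arrays lay above all 4 vehicle arrays. Pcdh10 and Camk2n1 lay under the 95th percentile of negative-control probes on all 4 vehicle arrays, and Camk2n1 also on 2 citrus arrays. Background therefore bounds the sizes of their rises. S100a5 was 0.57 ± 0.13 higher, with all citrus arrays above all vehicle arrays and an exact permutation p of 0.0286, but it did not pass over all genes (adjusted p = 0.66). Omp was at −0.02 ± 0.14 (adjusted p = 1). Sema7a did not pass with arrays centred on the receptor median (adjusted p = 0.0889). The call of Olfr353 was lost without citrus replicate 2 (adjusted p = 0.395) or 3 (0.0884) and without vehicle replicate 1 (0.282), 2 (0.243), 3 (0.248) or 4 (0.147). Its levels of 7.15 in citrus and 5.32 in vehicle lay below the 95th percentile of negative-control probes.

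Of 15 activity-linked OSN genes, 2 rose in GFP-positive cells with citrus, Pcdh10 and Sema7a, and 3 adjusted over the list alone (camera 4.7e-07, but adjusted p = 0.11 with an estimated correlation). Lrrc3b was at 1.03 ± 0.54 and Pcp4l1 at 0.62 ± 0.25, neither past the threshold. The same 2 genes rose among 14 axon sorting molecules (0.0078, but adjusted p = 0.739 with an estimated correlation). Kirrel2, an adhesion molecule, was at 0.52 ± 0.45. Also 2 rose adjusted over the list alone, and the list median of 0.08 became −0.17 with arrays centred on the receptor median. It was 0.01 without citrus replicate 3, 0.05 without citrus replicate 2 or vehicle replicate 1 or 2, and 0.12 without citrus replicate 4. In the synaptic vesicle list limma called 0 of 13 genes, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with Vamp2 at 0.40 ± 0.20 and Syn1 at 0.40 ± 0.25 (camera 0.029, but adjusted p = 0.915 with an estimated correlation). The median of 0.22 became −0.03 with that centring and 0.12 without vehicle replicate 2. In oxidative phosphorylation limma also called 0 of 19 in each of these counts, with a median of −0.13 that became −0.02 without vehicle replicate 2 and −0.19 without vehicle replicate 4 (camera 0.046, but adjusted p = 0.918 with an estimated correlation). Cox4i1 of complex IV was at −0.30 ± 0.21 and Ndufa2 of complex I at −0.30 ± 0.19. Odorant receptors had 754 of 1090 above 0 with a median of 0.17. It became −0.07 with arrays centred on the receptor median, which takes out any shift common to receptors. Of the 1090 odorant receptors 1 passed the threshold and 2 adjusted over the list alone (camera 8.7e-05, but adjusted p = 0.859 with an estimated correlation). Those 2 were Olfr353 and Olfr704 (1.79 ± 0.35, adjusted p = 0.3 over all genes). The largest differences, in Olfr1123 (2.87 ± 0.63, adjusted p = 0.56) and Olfr736 (2.36 ± 0.55, 0.66), did not pass although all citrus arrays lay above all vehicle arrays. The class II list gave 1 of 958, 2 adjusted over the list alone (0.00012, but adjusted p = 0.893 with an estimated correlation) with a median of 0.17 that became −0.08 with that centring. Class I gave 0 of 118 by limma, also 0 adjusted over the list alone and 4 at an unadjusted p under 0.05, with a median of 0.26 (camera 0.00092, but adjusted p = 0.918 with an estimated correlation). That median became 0.01 with that centring and 0.01 without citrus replicate 3. It was 0.13 and 0.12 without vehicle replicate 1 and 2, 0.40 without citrus replicate 2 and 0.50 without vehicle replicate 3. Olfr577 was at 0.94 ± 0.29 and Olfr594 at 0.82 ± 0.58. The number of lists called was 7 with the preset correlation, 4 without citrus replicate 3 or vehicle replicate 1, and 3 without vehicle replicate 2. The other lists had adjusted p of 0.128 or more.

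In cells sorted as GFP-negative, Pcdh10 rose by 3.57 ± 0.38 (adjusted p = 0.00051) and Sema7a by 1.29 ± 0.14 (0.00051). Olfr618, a class I receptor, fell by 2.77 on the log2 scale (SE 0.42, 0.027). All 4 citrus arrays lay above all vehicle arrays for the first pair and below them for Olfr618. In all, limma called 2 probe sets higher and 1 lower, with 1151 at an unadjusted p under 0.05. Camk2n1 (1.23 ± 0.28, adjusted p = 0.5) and S100a5 (0.61 ± 0.13, 0.44, exact permutation p = 0.0286) did not pass over all genes although all citrus arrays lay above all vehicle arrays. Omp was at 0.07 ± 0.14 (0.97). Whether any of these effects differed from those in GFP-positive cells is the test of the effect of citrus on enrichment. Sema7a did not pass when only the 2 GFP-negative groups were fitted (adjusted p = 0.0691). Olfr618 did not pass without citrus replicate 1 (adjusted p = 0.203), 2 (0.0858) or 3 (0.229) or vehicle replicate 1 (0.187), 3 (0.332) or 4 (0.196).

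Activity-linked genes were the first of 3 lists called in GFP-negative cells, with 2 of 15 higher and 4 adjusted over the list alone (camera 5.4e-05, but adjusted p = 0.313 with an estimated correlation). Lrrc3b was at 0.95 ± 0.54 and Kcnn2, a calcium-activated potassium channel, at 0.75 ± 0.21. Of 8 heat shock genes limma called 0, also 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, and all 8 were above 0 (camera 0.0043, but adjusted p = 0.458 with an estimated correlation). Hspa1a and Hspa1b, inducible HSP70 chaperones, were at 1.43 ± 0.87 and 1.51 ± 0.95. Class I receptors had 86 of 118 above 0 with a median of 0.25, and 0 rose and 1 fell by limma, also 0 and 1 adjusted over the list alone (camera 0.043, but adjusted p = 0.863 with an estimated correlation). Olfr33 was at 1.18 ± 0.43. The count of 3 lists became 11 without citrus replicate 1, 5 without citrus replicate 3, 1 without vehicle replicate 1, 7 without vehicle replicate 2, 9 without vehicle replicate 3 and 11 without vehicle replicate 4. The other lists had adjusted p of 0.0541 or more.

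Averaged over both gates, a comparison added after these values were seen, Pcdh10 rose by 3.90 ± 0.27 and Sema7a by 1.38 ± 0.10 (adjusted p = 1.0e-06 for both), Camk2n1 by 1.98 ± 0.20 (0.00011) and S100a5 by 0.59 ± 0.09 (0.031). The call of S100a5 was lost without citrus replicate 1 (adjusted p = 0.291), 2 (0.193), 3 (0.116) or 4 (0.14) and without vehicle replicate 1 (0.153), 3 (0.126) or 4 (0.215). It was also lost with the pool as a random block (0.0899), with arrays centred on the median (0.0714), on mature OSN markers (0.0733) or on the receptor median (0.977).

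The comparison the assay is built on asks which genes, above all receptors, gained in GFP-positive relative to GFP-negative cells with citrus. Olfr353 had the smallest p, at 2.77 ± 0.42 (95% interval 1.89 to 3.65): it lay between 0.45 and 2.27 in the citrus pools and between −1.73 and −1.32 in the vehicle pools. All 4 citrus pools were above all 4 vehicle pools. It rose adjusted over the receptor list alone (adjusted p = 0.0046) but did not pass over all genes (0.081), except without citrus replicate 1 (0.015). The call over all genes was also reached with arrays centred on mature OSN markers (0.027) or on the receptor median (0.021) and with a trended, robust prior (0.046). Over all genes limma called 0 probe sets. There 722 had an unadjusted p under 0.05, 376 higher and 346 lower, where chance gives 978.6. Of 1104 receptors 54 had, 45 higher and 9 lower, where chance gives 55.2. Olfr1284 was at 2.46 ± 0.54 in the main fit. With the pool as a block it was the 1 probe set that passed (adjusted p = 0.03 in the block fit). In the block fit 5 receptors passed adjusted over the list alone: Olfr1260, Olfr1284, Olfr353, Olfr1323 and Olfr190. The citrus pools lay between 3.25 and 3.85 and the vehicle pools between 0.69 and 1.73 for Olfr1284, and for Olfr704 (2.30 ± 0.49) between 0.59 and 2.74 and between −2.25 and −0.58.

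The receptors next in order of p, none past the threshold, were Olfr1200 (2.23 ± 0.56), Olfr1264 (1.74 ± 0.45), Olfr351 (1.31 ± 0.34), Olfr30 (1.65 ± 0.47), Olfr769 (−1.53 ± 0.44), Olfr618 (2.02 ± 0.59) and Olfr1260 (2.21 ± 0.66), each with adjusted p = 1 over all genes. S100a5 (−0.03 ± 0.18) and Omp (−0.09 ± 0.19) showed no detectable change of enrichment. Camk2n1 (1.51 ± 0.40), Pcdh10 (0.65 ± 0.54) and Sema7a (0.17 ± 0.20) did not pass, so that their citrus effects were not shown to differ between the gates. On all 4 vehicle arrays of either gate, Pcdh10 and Camk2n1 lay under the negative-control level used above. Background thus bounds their gate differences in vehicle, though signals under that level need not be background alone. The test therefore does not decide for Pcdh10 and Camk2n1 whether the citrus effects differ. Odorant receptors as a list had a median of 0.13, which became −0.17 with arrays centred on the receptor median. That centring takes out any shift common to receptors. With values as deposited the median was 0.02 without citrus replicate 3 and 0.04 without vehicle replicate 1, but 0.22 and 0.21 without citrus replicate 1 and 2. Limma called 0 of 1090, 1 adjusted over the list alone (camera 0.027, but adjusted p = 0.867 with an estimated correlation). Olfr1123 (2.98 ± 0.90) and Olfr736 (2.41 ± 0.77) had large differences that did not pass. The class II list had a median of 0.16, which became −0.14 with that centring, 0.07 and 0.11 without citrus replicate 3 and 4, and 0.06 without vehicle replicate 1 (camera 0.022, but adjusted p = 0.867 with an estimated correlation). Limma called 0 of 958, 1 adjusted over the list alone, with 40 higher and 8 lower at an unadjusted p under 0.05. The synaptic vesicle list had 12 of 13 genes above 0 with a median of 0.25, which became −0.05 with that centring and 0.11 without citrus replicate 4. Limma called 0 of 13, also 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. Syn1 was at 0.82 ± 0.36 and Vamp2 at 0.53 ± 0.29, and the list was called (camera 0.022, but adjusted p = 0.867 with an estimated correlation). The 3 lists became 1 without citrus replicate 3, 0 without citrus replicate 4 or vehicle replicate 1, and 5 without vehicle replicate 3 or 4. With the pool as a block 7 were called, adding the sustentacular (adjusted p = 0.036), heat shock (0.032), xenobiotic metabolism (0.036) and sex-linked (0.032) lists. With an estimated correlation 0 lists were called, at adjusted p of 0.867 or more without the block and 0.691 or more with it. The sustentacular and xenobiotic medians of −0.49 and −0.32 became −0.15 and −0.06 without vehicle replicate 1, in which these lists averaged 0.07 and 0.10 higher in GFP-positive cells, against −1.63 to −1.25 and −0.87 to −0.81 in the other vehicle pools. The xenobiotic median was −0.21 without citrus replicate 3. The heat shock median of −0.33 was −0.12 without citrus replicate 4, −0.11 without vehicle replicate 2 and −0.50 without vehicle replicate 4. The other lists had adjusted p of 0.167 or more.

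**Figure D4:**
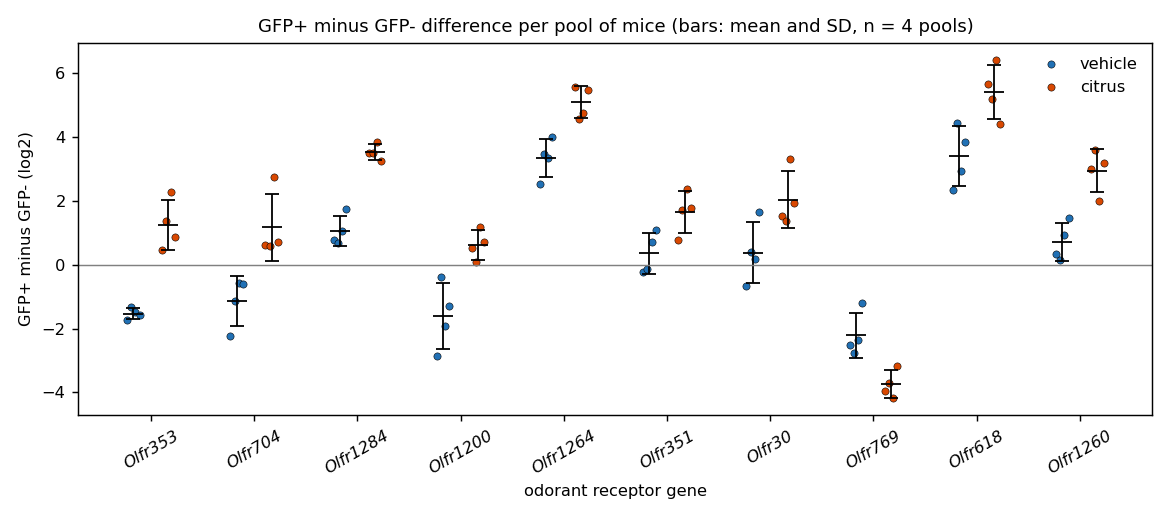
Difference between GFP-positive and GFP-negative cells (log2, y axis) per pool of 3 mice for the 10 receptors with the smallest p (x axis), with points for vehicle (blue) and citrus (orange) pools and bars for mean and SD (n = 4 pools). Olfr353 lies between 0.45 and 2.27 in citrus and between −1.73 and −1.32 in vehicle.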

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

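All tests of the patterns weighed here were chosen after the result was seen, except the splits of the pools for Olfr353 and for the receptor shift and the comparison of receptors with mature OSN markers. Among 348 groups of 4 arrays of the 87 named genes, 22 held an array far from the other 3, where chance gives about 1 in 20 groups, or 17.4.

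Vehicle GFP-negative replicate 1 stood apart in 5 genes. It held Sult1c1 at 7.11 against 11.93 to 12.05 and Cyp2a5 at 10.28 against 15.70 to 16.16. It also held Tmem176b at 9.91 against 11.26 to 11.44, Olfr704 at 7.19 against 6.03 to 6.23 and Olfr1264 at 14.53 against 13.31 to 13.40. In vehicle GFP-positive arrays, replicate 1 held Fxyd2 at 7.82 against 10.50 to 10.85. Replicate 2 held Kcnmb3 at 13.07 against 13.54 to 13.58 and Olfr1200 at 11.84 against 10.22 to 10.36. Replicate 4 held Sox9 at 5.10 against 5.37 to 5.41. Vehicle GFP-positive replicate 3 held Cidea at 11.41 against 11.97 to 12.08 and Olfr372 at 9.02 against 9.78 to 9.86. It also held Il1b at 4.11 against 5.53 to 5.58, Olfr69 at 8.82 against 5.96 to 6.12 and Camk2n1 at 7.13 against 6.21 to 6.30. Vehicle GFP-negative replicate 2 held Olfr309 at 6.92 against 9.30 to 9.77. In citrus GFP-positive arrays, replicate 3 held Ly6c2 at 3.38 against 5.0 to 5.24 and replicate 2 Syn1 at 9.32 against 9.89 to 9.98. In citrus GFP-negative arrays, replicate 1 held Fxyd2 at 6.19 against 6.74 to 6.84 and Hp at 12.04 against 13.71 to 13.98. Replicate 2 held Syn2 at 12.67 against 12.34 to 12.35 and Ndufa2 at 9.82 against 10.56 to 10.71. Replicate 3 held Olfr594 at 9.94 against 10.72 to 10.79.

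Pcdh10, Sema7a, Camk2n1 and S100a5 were higher with citrus when both gates were averaged. GFP-positive cells left in the citrus GFP-negative arrays could raise all 4 there. Pcdh10 would need about 25.6% of the RNA, which would hold every gate difference under about 1.96, as far as the stretched scale allows the sum. Of 468 receptors 148 (31.6%) had a lower 95% bound above it. This argues against such cells with the mean RNA of the GFP-positive arrays, but cannot weigh cells unlike that mean. The share has no interval and uses a vehicle level of Pcdh10 under the 95th percentile of negative-control probes. More sensory neuron RNA in the citrus arrays is argued against by the mature OSN markers, which differed by 0.0141 (95% interval over pools −0.13 to 0.16) against a lower bound of 0.46 for S100a5. Chance is not excluded by the count of genes: 4 of 35 splits of the pools gave at least the real 4 genes, the highest other split 12, although the smallest p of the real split was 5.3e-11 against 3.2e-09 in all other splits. An effect of citrus on OSNs of both gates may be behind it and stays open, as a hypothesis.

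Olfr353 was marked because its citrus effect differed between the gates by 2.77 in a test of the difference itself. A single deviating pool is argued against, since adjusted p over the list alone stayed between 0.00085 and 0.0461 without any 1 pool, at log2 2.42 to 3.03. Probe signal from the related neighbour Olfr351 cannot be told apart from a change of Olfr353: the difference of 1.46 between both genes (95% interval over pools 0.52 to 2.40) compares unlike probe sets on a scale that can be stretched, with Olfr353 under the 95th percentile of negative-control probes. Chance is not excluded: 7 of 35 splits of the pools called at least 1 receptor adjusted over the list alone, the highest other split 24, which points to a structure of the samples that this count does not separate from citrus. A gain of Olfr353 neurons in the GFP-positive gate with citrus may account for the change, but remains untested beyond these arrays.

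Odorant and trace amine receptors had a median citrus effect on enrichment of 0.13, but 0.02 without citrus replicate 3, 0.04 without vehicle replicate 1, and 0.22 and 0.21 without citrus replicate 1 and 2. More sensory neuron RNA in the citrus GFP-positive relative to the GFP-negative arrays could account for this and cannot be told apart from a receptor effect: the receptor mean exceeded the mature OSN mean by 0.0826, with a 95% interval over pools from −0.23 to 0.39. Chance is not excluded either, since 16 of 35 splits gave a median as far from 0, the highest other split 0.31. With arrays centred on the receptor median these receptors lay at −0.18, but that centring takes out any shift common to receptors, so it cannot weigh one. Negative-control probes of GFP-negative arrays were lower with citrus at their 95th percentile, and their part in this shift was not tested.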

How the results depend on the processing

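Camera with the pool as a block, medians of lists without single pools, and all values of the citrus difference averaged over both gates were chosen after the results were seen. The other alternatives were planned. The cause of these changes was not tested. The effect on enrichment went from 0 to 1 probe set, the receptor Olfr353, with a trended and robust prior, with arrays centred on mature OSN markers and with arrays centred on the receptor median. It went to 1, Olfr1284, with the pool as a block. Without single pools it lay between 0 and 1, over all genes and over receptors alike. Adjusted over the receptor list alone, 1 receptor became 2 with mature OSN centring, 2 with receptor median centring, 5 with the pool as a block and 4 with the number shared by citrus and vehicle pools as a block. For GFP+ vs GFP- cells in vehicle 3723 probe sets became 8635 with median centring (7080 higher, 1555 lower). Without single pools it was 2369 to 3675. For GFP+ vs GFP- cells in citrus 3569 became 10839 with median centring (9128 and 1711) and 11185 with receptor median centring (398 and 10787). Without single pools it was 2477 to 3672. The share of calls that were higher was 47.6% in vehicle and 40.8% in citrus as deposited, 82.0% and 84.2% with median centring. It was 32.7% and 28.4% with cyclic loess, 14.8% and 12.4% with mature OSN centring, and 9.58% and 3.56% with receptor median centring. Each scaling moves the other genes with what it fixes. The median of all genes, 0.11 in vehicle and 0.13 in citrus, became 0.39 and 0.46, 0.02 and 0.03, −0.18 and −0.23, and −0.35 and −0.63 in that order. Receptor median centring moved it from −0.01 to −0.31 in the effect on enrichment and from 0.01 to −0.24 for citrus in GFP-positive cells. Citrus changed 3 to 6 genes in GFP-positive cells and 2 to 3 in GFP-negative cells under all alternatives. Camera lists called went from 3, 7 and 3 in the effect on enrichment, GFP-positive and GFP-negative cells to 0, 0 and 0 with an estimated correlation and 0, 1 and 1 with fry. They went from 19 in vehicle and 21 in citrus to 6 and 7 with an estimated correlation, and to 23 and 24 with fry. With the pool as a block the 3 became 7, and with the block and an estimated correlation together the effect on enrichment, vehicle and citrus had 0, 0 and 0. Without single pools they were 0 to 5, 3 to 7, 1 to 11, 17 to 21 and 20 to 21. For 156 results of named genes, 2796 values were computed. Of these 2694 kept direction and side of the threshold, 71 lost and 18 gained a call, and 13 turned sign. Omp in vehicle turned to −0.026 with mature OSN and −0.194 with receptor median centring, and in citrus to −0.185 and −0.582. With receptor median centring Ano2 turned to −0.048 and Gng13 to −0.149 in citrus. The effect on enrichment of S100a5 turned to 0.010 with median centring and ranged from −0.116 to 0.049 without single pools, and that of Omp from −0.162 to 0.0045. Omp ranged from −0.038 to 0.018 in GFP-positive and from −0.022 to 0.142 in GFP-negative cells. With receptor median centring Ano2, Rtp2, Sdha and Atp5j in vehicle and Pde1c, Syn2 and Syn1 in citrus did not pass (adjusted p = 0.548, 0.336, 0.205, 0.268, 0.411, 0.238 and 0.622). Olfr353 in GFP-positive cells was lost with all probe sets tested (0.0992), median centring (0.0548) and the shared number as a block (0.0729). Olfr618 in GFP-negative cells was lost with a trended and robust prior (0.0557), array weights (0.0559), all probe sets (0.122) and only the groups compared (0.437). The pool as a block changed no other call than those given in the report. The numbers shared by citrus and vehicle pools gave correlations from −0.013 to 0.354, and arrays taken as one pool 0.075 to 0.275. These values do not tell both kinds of pairing apart. The shared number entered only as an alternative. In GFP-positive arrays, replicate 3 stood apart in both stimuli in some lists, picked after they were seen. Class I receptors averaged 8.30 with citrus and 8.12 in vehicle there, against 6.85 to 7.44 on the other arrays. Dorsal OSN genes averaged 15.71 and 15.75 there, against 14.67 to 15.33. In GFP-negative arrays class I did not stand apart, at 6.66 and 6.90 against 6.54 to 7.08. The cause of this likeness by number was not tested. That 3 of 4 citrus arrays in each gate correlated best with their own number is a hint from the data, not from the design. Signal over background limits dim receptors: per array 252 to 458 of 1104 lay above the 95th percentile of negative-control probes.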

Other observations

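The test of a citrus response shared within receptor families, the comparison of the smallest p between splits and the lists set beside single splits were chosen after the results were seen, and the other tests of this part before. Splits of the pools set the counts of called genes against chance. In the gate comparisons 1 of 35 splits, the real one, gave as many probe sets as observed, 3723 in vehicle and 3569 in citrus. The highest other split gave 0. The other splits mix the gates within a group, which widens the spread, so few calls were likely in them from the start. Of the 8 splits that part every pair of arrays of a pool, the real one included, the highest other also gave 0. With arrays taken as pairs, 8 splits are too few to exclude chance by this count. For the effect on enrichment the real count was 0, so that all 35 splits reach it by construction and the count says nothing about chance. The highest other split gave 1 over all genes and 0 over receptors. Citrus in GFP-positive cells called 4 genes, 2 of 35 splits gave as many and the highest other gave 18. In GFP-negative cells it called 3, 4 of 35 splits gave as many and the highest other gave 48, so chance is not excluded by the counts. The split with 18 genes, 17 of them receptors, sets citrus and vehicle replicates 1 and 3 against the others, so it follows the numbers in the labels. The same split gave 9 genes in GFP-negative cells, 5 of them in the immediate early list. A split of citrus replicates 1 and 2 and vehicle replicates 1 and 3 against the others gave 24 there. That with 48 sets citrus replicate 1 and vehicle replicates 1, 2 and 3 against the others. Splits with so many genes point to a structure of the samples beside the stimulus. In GFP-negative arrays the split with 48 genes also parted the list means without overlap, at 10.60 against 11.52 for myeloid and lymphoid and 6.32 against 7.79 for sex-linked genes. Of its 48 genes 0 lay on chromosome X and 0 on Y by limma, and the 3 sex-linked genes did not pass in it (adjusted p = 0.0847 to 0.158). Between citrus and vehicle the sex-linked genes averaged 0.50 higher in GFP-negative cells, with 0 of 3 past the threshold by limma and 0 at an unadjusted p under 0.05. The list means of single GFP-negative arrays overlapped, at 5.97 to 7.98 with citrus and 5.70 to 7.90 in vehicle. The share of white blood cells and the sexes in a pool, which the labels do not give, stay open and untested. The smallest p of the real split was 3.3e-09 against 1.4e-08 in GFP-positive and 3.9e-08 against 4.0e-09 in GFP-negative cells.

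If neurons of responding receptors cross from the GFP-negative into the GFP-positive gate, receptors that are higher with citrus in one gate might be lower in the other. Across 1104 receptors the correlation of the citrus changes in both gates was 0.0206, lower than the median of 0.191 over the other 34 splits (−0.004 to 0.391), but 4 of those were as low, so these pools do not decide it. Receptors are not independent replicates.

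In the effect on enrichment, where 0 of 1104 receptors passed, values were alike within MOR families. Families accounted for 24.4% of the variance over 1006 receptors in 159 families, against a median of 15.7% and a 95th percentile of 18.7% over 10000 shuffles (permutation p = 1e-04, the smallest they can give). Since 19 of the 34 other splits of the pools gave a share as high (median 24.9%, 15.1 to 36.3%), this likeness appears under other groupings too and does not point to citrus.

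The gate differences in vehicle and in citrus correlated across genes at r = 0.95, and across receptors at 0.98; genes are not independent replicates. Of the probe sets without a symbol, 96 were higher and 158 lower in GFP-positive cells in vehicle, and 81 and 184 in citrus. Of the control probes, 163 and 36 were past the threshold in vehicle, 119 and 32 in citrus, and 0 and 3 for citrus in GFP-positive cells by limma. In some lists the median, the mean and the direction of the test differed in sign. There were 3 in the effect on enrichment (stroma, class I receptors, vomeronasal receptors), and 5 for citrus in GFP-positive cells (horizontal basal, microvillous, myeloid and lymphoid, endothelium, sex-linked). A further 5 in GFP-negative cells (horizontal basal, ensheathing glia, axon sorting, oxidative phosphorylation, class II receptors), 2 in vehicle (endothelium, NRF2 targets) and 3 in citrus (stroma, NRF2 targets, sex-linked).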
